A study of Mus musculus with 91 samples.

How the data were processed

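The labels describe 91 libraries of sorted mouse cells, prepared as 3' end mRNA libraries from total RNA, in which read 2 carried the sample barcode and the molecular identifier. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq, aligned with Bowtie2 to mm9 and quantified with HOMER, with no versions given. Whether molecular identifiers were collapsed, how strand was handled and which reads were dropped are not given in the sources used here, so genes that overlap or lie antisense cannot be told apart. The deposited signal values, per the file headers, are HOMER tag counts for each RefSeq gene scaled to 10000000 aligned tags per library, in 4 tables with 1 column per library. The bracketed number in each column name was taken as the worth of 1 read, which no label states. Divided by it, 100% of the low values of every library were whole within 0.05, so that reads were recovered; over all values the lowest share was 100% in the Timeline and poly I:C tables, 94.348% in the germ-free table and 72.191% in the Mafb table, where large values had been rounded. Reads in genes and the worth of a read set the precision of each value; the listed genes held 39.83% to 63.66% of the scaled tags of a library. Replicates of a group differed by more than counting error, with a mean chi-square per gene of 1.42 to 19.4 over 143 pairs of libraries.

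All 91 columns matched a sample and 0 were left out. Samples were grouped by source name, giving 33 groups, and the Timeline groups were placed in 4 classes: yolk sac (n = 8), early brain to E13.5 (n = 7), later brain from E14.5 to postnatal day 9 (n = 9) and adult (n = 6). The test planned for count tables was edgeR's; since the tables hold scaled values, the fallback set out in the same plan was used, limma-trend on log2(value + 1), and the edgeR quasi-likelihood test on recovered reads was added as an alternative. Genes with a value of 50 or more in at least as many libraries as the smallest group of the fit (and at least 2) were tested, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design, the 22 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Entries with identical values in the groups compared were all tested and counted, and only the first could be named among the largest changes.

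The 19 comparisons were 3 between successive classes, 2 trends over embryonic day, an F test across adult regions, 4 of poly I:C groups, 4 of germ-free groups and 2 of Mafb groups, and the interaction of treatment and age in each of the 3 perturbations. All groups of the germ-free table shared 1 estimate of spread, as did those of the Mafb table and the Timeline classes, while the poly I:C table was split by age except for the interaction, and a group with a single library was assumed to vary like the others. Stages within a class counted as its replicates. Gene lists were tested with camera at a preset correlation of 0.01 and again with the correlation estimated, and their members were counted over all genes tested and adjusted over the list alone. With the preset correlation 129 of 379 list tests passed. The 6 developmental lists hold up to 100 genes each way of smallest p at 2-fold or more from the Timeline comparisons. Lists of skeletal muscle genes were added: the first 20 were written after muscle transcripts had been seen, and 26 further genes before their values were looked at.

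Named genes are, per comparison, Mafb in the knockout tables, the 8 rising and 8 falling genes of largest change among those with an adjusted p under 0.05, a mean of at least 200 in the higher group and no overlap between the groups' libraries (no such demand in the interactions), up to 4 members of each fixed list by smallest p, and 15 genes allowed throughout. Predicted genes and clone names were passed over, and where fewer than 5 genes passed the 5 of smallest p were named.

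Near-identical copies were sought with minimap2 2.31-r1302 in an annotation of another build (GRCm38). The last 400 bases of each gene's transcript were aligned to all annotated transcripts, pseudogenes among them. Hits of at least 60 aligned bases and 97% identity in other genes were counted. Copies absent from the annotation would be missed. Of 20129 genes 19898 (98.9%) could be searched and 1388 (6.98%) had a copy. Reads of such genes may be split between copies, and their values are uncertain. This applies to Gapdh (45 copies), Ppia (16), Rpl13 (5), Rplp1 (2), Gpx4 (1), Rpl8 (1), Cma1 (1) and Mki67 (1). No coordinates are given, since the tables use another build.

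Each test was tested on simulated data, reads drawn around the real means with 200 genes changed, 100 of them 2-fold and 100 4-fold. Within a comparison all genes had the same dispersion and, apart from the planted changes, all groups the same mean. Genes varied independently, and no stages, library sets or deviating libraries were simulated. The rates below hold for that simpler setting and may differ in the real data. For the classes limma recovered 60, 62 and 57 of the 2-fold and 100, 97 and 98 of the 4-fold changes (early brain against yolk sac, 8637 genes; later against early brain, 8636; adult against later brain, 8630). For the trends the planted change was 2-fold or 4-fold per embryonic day, so their recovery is not comparable with that of the groups. The yolk sac trend (8370 genes) gave 99 and 100 and the early brain trend (8299) 91 and 100. Adult regions (7753) gave 44 and 94. Poly I:C at E14.5 in newborns (8598 genes) gave 39 and 95, at E12.5 against PBS (8588) 65 and 92, between injection days (8591) 68 and 95, at 4 weeks (8719) 32 and 88 and by age (8981) 4 and 44. In germ-free newborns (8815 genes) it gave 36 and 95, at 4 weeks (8833) 13 and 85, at 6 weeks (8838) 49 and 100, at 8 weeks (8839) 6 and 85 and by age (8842) 20 and 79. In Mafb newborns (8484 genes) it gave 85 and 100, at 5 weeks (8514) 69 and 100 and by age (8503) 33 and 98. A wrong direction was called in 0 cases. Unchanged genes made up 2.19% to 15.7% of the limma calls and over 5% in 13 of 19 comparisons, the most being 36 of 235 in the yolk sac trend, 17 of 108 in germ-free animals at 8 weeks and 20 of 151 in germ-free newborns.

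The alternatives tried were TMM and DESeq2 size-factor scaling of the values, no filter on low values, pseudocounts of 0.1 and 10, DESeq2 and edgeR tests on recovered reads, leaving out each library in turn, leaving out the shallowest libraries, fitting the compared groups alone, label numbers as a block, and lists of 50 and 200 genes. Chosen after seeing the data were edgeR, TMM, a block or omission for library sets, genes without copies only, removal of each library's trend on GC content, omission of Mafb knockout 5-week libraries 1 and 2 together, and omission of the 20 muscle genes. R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.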

Results

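The series measured mRNA by 3' end sequencing in sorted mouse cells of the microglial lineage, in 91 libraries that form 33 groups across 4 tables. The Timeline table held 30 libraries of CX3CR1-GFP+ cells: yolk sac progenitors at E10.5, E11.5, E12.5 and E13.5 (2 libraries each), brain at E10.5, E11.5, E12.5, E16.5 and postnatal days 3, 6 and 9 (2 each), and brain at E13.5 and E14.5 (1 each). It also held cortex, hippocampus and spinal cord of adults at 8 weeks (2 each). Yolk sac and early brain cells were gated as CD45+CD11B+ and later cells as CD45int CD11Bint. The other tables held CD45int CD11Bint microglia from 3 perturbations. Poly I:C, a synthetic double-stranded RNA used to mimic viral infection of the mother, was given to pregnant females at 5 mg/kg. This table held 23 libraries: newborns after PBS at E14.5 (n = 2), poly I:C at E14.5 (n = 2) or poly I:C at E12.5 (n = 5), and 4-week animals after PBS (n = 2) or poly I:C (n = 12) at E14.5. Germ-free housing was compared with control housing in newborns (3 and 3 libraries) and at 4 weeks (2 and 2), 6 weeks (5 and 4) and 8 weeks (2 and 2). Knockout of Mafb, a transcription factor of the macrophage lineage, was compared with controls in newborns (6 and 3 libraries) and at 5 weeks (3 and 3). Whether libraries of a group came from separate animals was not stated.

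Values are tags per gene scaled to 10000000 aligned tags per library. Reads recovered in genes ranged from 204670 to 2278927 in the Timeline table, 836191 to 1397823 in the poly I:C table, 831961 to 2517119 in the germ-free table and 1424900 to 4446774 in the Mafb table. The shallowest were both brain E10.5 libraries, which lay under 270829 reads, a threshold set at a fraction of the Timeline median of 812487. A single read was worth 21 units in the shallowest library and 1.143 in the deepest, so values of a few units rest on single reads.

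The first comparison asked how cells in the early brain (E10.5 to E13.5, n = 7) differ from yolk sac cells of the same days (n = 8). Genes of the microglial programme were higher in the brain. Tmem119, a surface marker of microglia, measured 2110 ± 2170 (SD, n = 7) in early brain and 79.6 ± 25.6 (n = 8) in yolk sac, a log2 difference of 4.35 (SE 0.29, limma adjusted p = 2.2e-12). Sall1, a transcription factor required for microglial identity, measured 228 ± 377 against 1.38 ± 3.91 (adjusted p = 6.9e-06), with 1070 in the single E13.5 library and 0 to 179 in the other 6. Serpine2, a secreted protease inhibitor, rose by 6.66 on the log2 scale (SE 0.67, adjusted p = 2.1e-08; 1120 ± 1190 against 17.0 ± 17.9), and Olfml3 and Spint1 rose by 3.83 and 4.9. Afp, a product of yolk sac endoderm, measured 337 ± 205 in yolk sac and 19.3 ± 39.6 in brain (log2 change -5.58, adjusted p = 4.8e-05). The complement receptor C5ar1 fell by 2.4 on the log2 scale (adjusted p = 4.9e-07).

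Of 26 microglial homeostatic genes measured, 17 were higher in early brain, 0 lower and 9 did not pass (21 and 0 adjusted over the list alone; median log2 change 1.49, camera adjusted p = 1.9e-27, and 0.023 with an estimated correlation). The purinergic receptor P2ry12 (1.70, adjusted p = 0.00048), Siglech (3.41, adjusted p = 2.1e-08) and Slc2a5 (3.66, adjusted p = 1.6e-08) were among them. Interferon-response genes were lower in brain: 16 of 30 fell and 0 rose (29 adjusted over the list alone; median log2 change -1.88, camera adjusted p = 2.5e-20; adjusted p = 0.094 with an estimated correlation). Ifit2 measured 40.1 ± 27.2 in brain and 617 ± 586 in yolk sac (adjusted p = 0.0028), and Stat2 354 ± 63.9 and 1270 ± 778 (adjusted p = 0.0026). The gap grew with age: the mean log2 level of the list was 5.43 in brain and 5.75 in yolk sac at E10.5, 6.39 and 7.46 at E11.5, 7.02 and 9.65 at E12.5 and 5.61 and 9.68 at E13.5. Ifit1 at E10.5 was higher in brain (62.8 ± 30.5, from 2 and 4 reads, against 21 ± 8.8). MHC class I genes followed with 6 of 12 lower and 0 higher (median log2 change -0.96, camera adjusted p = 2.2e-06; adjusted p = 0.19 with an estimated correlation). Markers of other cells moved as well. Of 8 neuron genes 5 were higher in brain (median log2 change 2.21, camera adjusted p = 2.1e-06, and 0.023 with an estimated correlation), among them Elavl3 at 184 ± 126 in brain and listed at 0 in yolk sac. In the erythroid list 3 of 12 were lower (camera adjusted p = 1.4e-05; adjusted p = 0.16 with an estimated correlation). Of 21 ribosomal protein genes 12 were higher in brain (camera adjusted p = 9.5e-10; adjusted p = 0.074 with an estimated correlation), but the brain E11.5 and E12.5 libraries stand apart in these transcripts and the difference of Rpl13 was 0.00 without them.

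In all, 747 of 8831 genes passed the threshold, 464 higher and 283 lower in early brain, and 446 of them at 2-fold or more. The edgeR test called 1144 genes, of which 692 were shared. Leaving out the single brain E13.5 library gave 475, without the brain E11.5 and E12.5 libraries 498 genes passed, and with the library set as a block 597. With only both classes in the fit 226 genes passed, and with a mean for each stage 2343.

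Within the yolk sac, interferon-response genes had rising slopes over embryonic day. The interferon-induced Ifit1 measured 21 ± 8.8 at E10.5, 203 ± 88.1 at E11.5, 1020 ± 87.3 at E12.5 and 890 ± 389 at E13.5 (n = 2 each; slope 1.83 per day on the log2 scale, limma adjusted p = 0.00023). Ifi27l2a rose from 44.1 to 7520 (slope 2.6, adjusted p = 5.3e-06). Of 34 list members 32 rose and 0 fell (32 adjusted over the list alone; median slope 1.28, camera adjusted p = 3.2e-30; adjusted p = 0.11 with an estimated correlation). All 12 MHC class I genes measured rose (median slope 0.87, camera adjusted p = 1.6e-15, and 0.021 with an estimated correlation), with H2-D1 going from 1960 ± 131 to 15400 ± 1640 and B2m from 5370 ± 214 to 29400 ± 436. Spp1, which encodes osteopontin, went from 36.7 ± 32.5 to 4330 ± 750 and the folate receptor Folr2 from 202 ± 73 to 4060 ± 493. Of 23 damage-associated genes 14 rose and 0 fell (19 adjusted over the list alone, camera adjusted p = 1.2e-10, and 0.045 with an estimated correlation). Cell cycle genes went the other way: 19 of 33 fell and 0 rose (25 adjusted over the list alone; median slope -0.43, camera adjusted p = 3.5e-14; adjusted p = 0.14 with an estimated correlation). The progenitor marker Cd34 fell from 497 ± 70.2 to 32.4 ± 16.8 (slope -1.28, adjusted p = 0.00014). Adult-type haemoglobin Hbb-b1, a red blood cell product, rose over the same days from 43.5 to 12300. The entry Hbb-bs had the same means at E10.5 and E13.5, so both entries may rest on the same reads. Of 13 erythroid genes 8 rose while 1 fell. In total 1276 of 8554 genes had a slope past the threshold, 828 rising and 448 falling (edgeR 1119, 972 shared). The count was 623 without yolk sac E10.5 library 1 and 558 without library 2.

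Homeostatic and immediate early transcripts had rising slopes over embryonic day in early brain. For Tmem119 and Cx3cr1 the largest step lay at E13.5, a single library. Tmem119 measured 772, 1690, 1440 and 6940 at E10.5, E11.5, E12.5 and E13.5, against 6820 in the single E14.5 library. Cx3cr1 measured 4480, 5690, 6030 and 13400, against 11700 at E14.5. Hexb (481, 1530, 1730 and 4300) had already risen by E11.5. A steady daily gain is therefore not shown, and the E11.5 and E12.5 libraries are of another library set. Sparc rose from 698 ± 25.9 (n = 2) to 13300 at E13.5 (n = 1; slope 1.32 per day, limma adjusted p = 0.0013). Olfml3 rose from 333 ± 113 to 5550 (adjusted p = 0.0038) and the immediate early gene Egr1 from 10 ± 15 to 2130 (adjusted p = 0.0065). Emb fell from 2850 ± 237 to 131 (slope -1.26, adjusted p = 0.003) and Prtn3, a granule protease of myeloid progenitors, from 649 ± 364 to 16.9 (slope -1.60, adjusted p = 0.002). Of 26 homeostatic genes 19 rose and 0 fell (23 and 1 adjusted over the list alone, camera adjusted p = 8.9e-15). Of 33 cell cycle genes 17 fell and 0 rose, including Pcna (slope -0.57, adjusted p = 0.0038; camera adjusted p = 2.7e-08). Immediate early genes rose in 10 of 20 cases and fell in 0 (12 adjusted over the list alone, camera adjusted p = 4.6e-07). None of these list calls held with an estimated correlation (adjusted p = 0.28 for each). Haemoglobin Hbb-b1 rose here as well, to 11600 at E13.5 (adjusted p = 0.0083). There were 1484 genes past the threshold among 8438, 573 rising and 911 falling, and 890 rising and 542 falling under TMM scaling. The count was 982 without brain E10.5 library 1, 828 without library 2, 985 without brain E12.5 library 2 and 1171 without brain E13.5. Without both E10.5 libraries limma called 0 genes, with 2058 at an unadjusted p under 0.05.

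**Figure D1:**
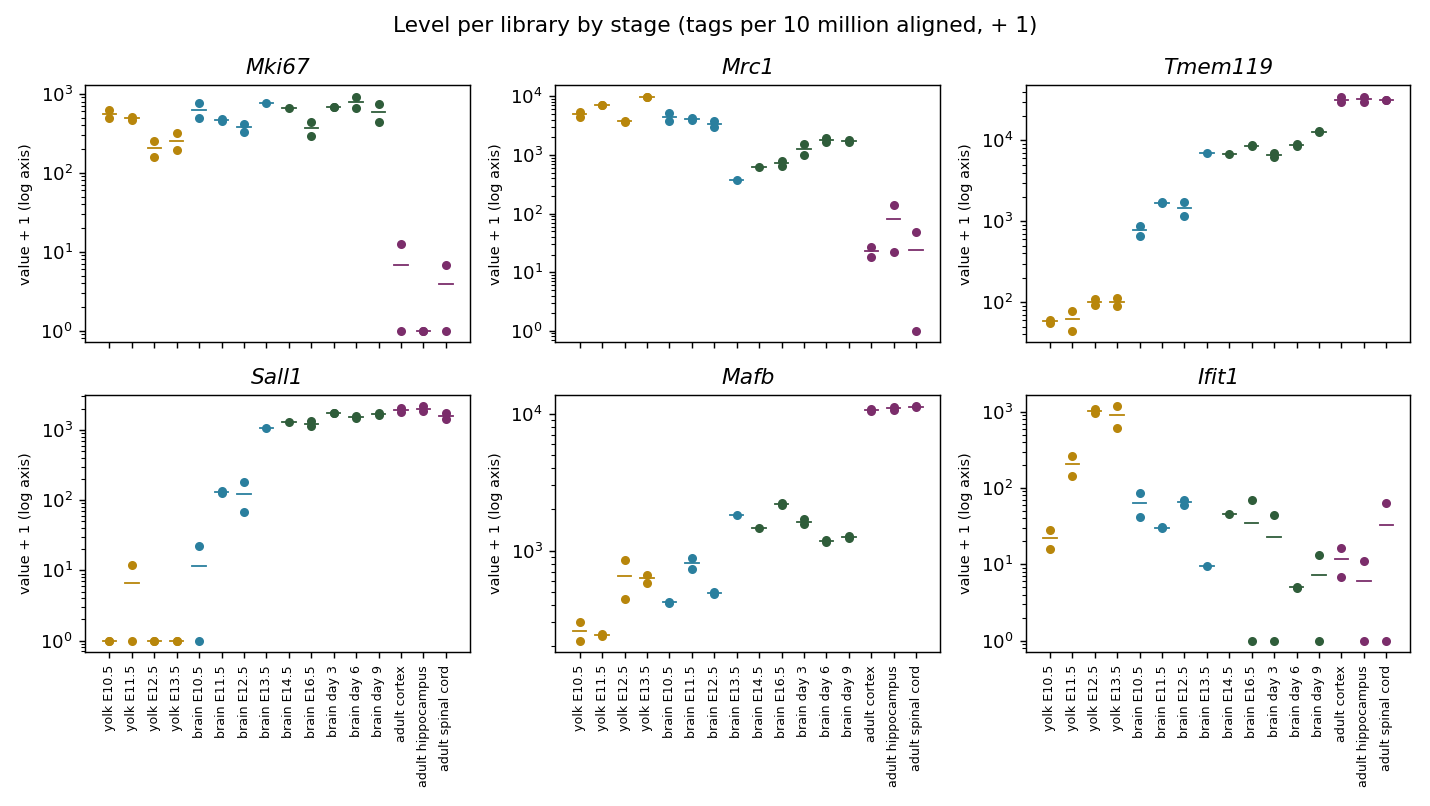
Values of 6 genes (value + 1, log axis; tags per 10000000) in each of the 30 Timeline libraries, ordered by stage or adult region on the horizontal axis, with a bar at the mean of each group. Mki67 falls to 2.89 in adults from 612 in later brain, while Mafb reaches 10900 in adults from 1550 in later brain.

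The move from early brain to later brain (E14.5 to postnatal day 9, n = 9) gave 4634 genes past the threshold, the most of the 19 comparisons. Microglial genes continued to rise. Sall1 reached 1520 ± 222 from 228 ± 377 (log2 change 4.53, SE 0.75, limma adjusted p = 1.1e-05), the purinergic receptor P2ry13 8770 ± 2120 from 1050 ± 1570 (3.75, adjusted p = 8.2e-10) and Tmem119 8930 ± 2390 from 2110 ± 2170. Genes of early macrophages fell: Lyve1, a hyaluronan receptor of border macrophages, measured 3340 ± 3120 in early and 19.5 ± 49.1 in later brain (-9.12, adjusted p = 2.2e-07), and F13a1 6180 ± 3160 and 30.8 ± 55.9. The RNA-binding protein gene Igf2bp1, active in embryonic cells, measured 1470 ± 636 and 65.4 ± 146 (-7.78, adjusted p = 1.5e-07). The intermediate filament gene Vim fell by 4.7 on the log2 scale (adjusted p = 3.6e-09).

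Homeostatic genes rose in 24 of 26 cases and fell in 0 (24 adjusted over the list alone; median log2 change 2.4, camera adjusted p = 7.8e-15; adjusted p = 0.27 with an estimated correlation). Border macrophage genes fell in 13 of 17 cases and rose in 0 (15 adjusted over the list alone; median -2.81, camera adjusted p = 9.6e-05; adjusted p = 0.4 with an estimated correlation). Immediate early genes rose in 13 of 22 cases and fell in 2 (camera adjusted p = 0.00011; adjusted p = 0.43 with an estimated correlation), with Junb at 8040 ± 2450 against 1090 ± 1690 and Jun at 4480 ± 1730 against 859 ± 431. Of 17 complement and pruning genes 11 rose and 1 fell (camera adjusted p = 5.3e-05; adjusted p = 0.27 with an estimated correlation), among them the integrin subunit genes Itgb2 (1.89, adjusted p = 7.7e-07) and Itgam (1.68, adjusted p = 6.4e-07). Replication genes fell, as in Mcm6 (-1.76, adjusted p = 1.3e-07) and 17 of 33 cell cycle genes against 1 that rose (camera adjusted p = 0.0065; adjusted p = 0.7 with an estimated correlation). The proliferation marker Mki67 did not pass (612 ± 191 in later brain, adjusted p = 0.71). Up and down calls were 2003 and 2631, or 2298 and 2339 under TMM scaling, and edgeR called 4978, of which 4331 were shared. The sorting gate changed between these classes, so that gate and age cannot be told apart. Library set differed in part as well. The brain E11.5 and E12.5 libraries held Rpl13, Rplp1 and Rpl8 at sums of 1501 to 2145, against at most 3 in later brain.

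Adult microglia (8 weeks, n = 6) held proliferation genes at far lower levels than the later brain (n = 9). Mki67 measured 2.89 ± 4.83 in adults and 612 ± 191 in later brain (limma adjusted p = 1.3e-15), and Nusap1, a spindle protein gene, was listed at 0 in adults against 273 ± 101. All 33 cell cycle genes measured fell (33 adjusted over the list alone; median log2 change -5.20, camera adjusted p = 3e-32, and 0.013 with an estimated correlation). Mafb rose to 10900 ± 315 from 1550 ± 408 (log2 change 2.86, SE 0.28, adjusted p = 6.9e-10), Upk1b to 704 ± 332 from 16.7 ± 17.3 (6.04, adjusted p = 6.9e-08) and Thrsp to 945 ± 271 from 16.8 ± 22.2 (7.22, adjusted p = 1.7e-08). The apolipoprotein gene Apoe fell to 1010 ± 276 from 13100 ± 6620 (-3.6, adjusted p = 8.3e-10), the mannose receptor gene Mrc1 to 41.9 ± 50.6 from 1290 ± 522 and Gpx3 to 47.8 ± 88.7 from 2210 ± 831.

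Tmem119 rose further, to 31800 ± 2270, whereas Sall1 measured 1830 ± 250 and did not pass (adjusted p = 0.8). Transcription factor genes rose in 10 of 27 cases and fell in 1 (camera adjusted p = 0.00012; adjusted p = 0.22 with an estimated correlation), with Mef2a at a log2 change of 1.86 (adjusted p = 5e-12). MHC class II genes rose in 5 of 8 cases (6 adjusted over the list alone; median 2.01, camera adjusted p = 0.0022; adjusted p = 0.3 with an estimated correlation), with H2-Aa at 588 ± 403 against 13.3 ± 11. Cholesterol and lipid genes fell in 9 of 17 cases and rose in 2 (camera adjusted p = 0.041; adjusted p = 0.22 with an estimated correlation), among them Ldlr and Fasn. Of 8831 genes 3553 passed, 1108 higher and 2445 lower in adults, or 1412 and 2136 under TMM scaling. TMM scaling moved the median of all genes from -0.185 to -0.065. The edgeR test called 4082 genes, 2119 higher and 1963 lower (2985 shared), so the excess of lower genes depends on the method. All adult libraries held the transcripts Rpl13, Rplp1 and Rpl8 at a sum of at least 391, against at most 3 in the later brain, so that the library set differs between these classes. The change was also seen within 1 other set. Of the 1108 higher and 2445 lower genes, 74.5% and 75.9% moved the same way from newborns to 4 to 8 weeks in controls of the germ-free table (48.1% and 51.5% of all genes). Library set alone therefore does not account for the whole adult pattern.

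Among adult regions, spinal cord had the mean farthest from the other 2 for 105 of the 114 genes that passed, cortex for 5 and hippocampus for 4 (n = 2 each). The immediate early gene Fos measured 17200 ± 1860 in spinal cord, 5950 ± 289 in cortex and 6210 ± 774 in hippocampus (limma F test, adjusted p = 4e-06). The transcription factor gene Klf2 measured 1690 ± 152, 255 ± 74.3 and 391 ± 101 (adjusted p = 2.3e-05). Spinal cord was lower for Fcrls (7970 ± 509 against 17300 ± 2400 and 18400 ± 307), P2ry12 (9160 ± 880 against 14400 ± 661 and 18600 ± 1110) and the cholesterol exporter gene Abcg1 (304 ± 83.9 against 1230 ± 4.54 and 1080 ± 49.4). Tmem119 and Mafb did not pass (adjusted p = 0.99 and 0.91). The 114 genes were among 7857 tested, 76 with a difference of at least 2-fold between 2 regions, and edgeR called 111, of which 68 were shared. The count was 60 without spinal cord library 2, 55 and 68 without cortex libraries 1 and 2, and 57 and 54 without hippocampus libraries 1 and 2.

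The poly I:C groups address how immune activation of the mother affects microglia of the offspring. Newborns after injection at E14.5 (n = 2) were compared with 2 PBS newborns. The chemokine receptor Ccr5 measured 1080 ± 96.3 after poly I:C and 91.4 ± 33.6 after PBS (log2 change 3.60, SE 0.23, limma adjusted p = 4.6e-09), and P2ry13 2450 ± 270 and 534 ± 110 (2.21, adjusted p = 4.6e-09). Cx3cr1 measured 25300 ± 505 and 12500 ± 30.6 (1.01, adjusted p = 1.1e-06) and Sall1 1220 ± 177 and 535 ± 35.2 (1.19, adjusted p = 9e-05). The stress-response regulator Nfe2l2 rose by 3.41 (adjusted p = 1.1e-06). Lower were the chemokine gene Cxcl10 (94.2 ± 55 against 777 ± 5.8, adjusted p = 0.00048), the replication gene Mcm5 (555 ± 79.6 against 1400 ± 38.1, adjusted p = 0.00014) and the neutrophil granule gene Ngp (5.54 ± 1.95 against 569 ± 592, adjusted p = 0.00013).

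Homeostatic genes were higher in 8 of 26 cases and lower in 1 (camera adjusted p = 0.00036; adjusted p = 0.072 with an estimated correlation). Cell cycle genes were lower in 10 of 33 cases and higher in 1 (median log2 change -0.32, camera adjusted p = 0.00039; adjusted p = 0.35 with an estimated correlation). Inflammatory genes were lower in 8 of 24 cases (9 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.00066; adjusted p = 0.28 with an estimated correlation). Monocyte and granulocyte genes were lower in 5 of 9, with 1 higher (camera adjusted p = 0.0003; adjusted p = 0.24 with an estimated correlation). The interferon-response list did not pass (4 of 29 higher, 1 lower, camera adjusted p = 0.52). In total 956 of 8857 genes passed, 648 higher and 308 lower, or 516 and 494 under TMM scaling, and edgeR called 1034 (801 shared). The count was 420 and 447 without PBS libraries 1 and 2, and 361 and 331 without poly I:C libraries 1 and 2. The PBS libraries held skeletal muscle transcripts: 20 muscle genes summed to 12887 and 8693 after PBS, 1365 and 7986 after poly I:C at E14.5, and 44 to 241 in all other libraries of the table.

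After injection at E12.5 the newborns (n = 5) had no PBS group of their own day, and were compared with the PBS newborns of E14.5 (n = 2). Ccr5 measured 1410 ± 230 (log2 change 3.97, limma adjusted p = 3.8e-12), P2ry13 5350 ± 393 (3.33, adjusted p = 2.8e-14) and Gpr34 3120 ± 403 against 364 ± 84.4 (3.10, adjusted p = 1.7e-12). Untreated newborn controls held Gpr34 at 730 ± 184 in the germ-free table and 4430 ± 926 in the Mafb table (n = 3 each). Its level after E12.5 thus lies within the range of untreated newborns. The transcription factor gene Jun rose by 1.69 (5140 ± 913 against 1580 ± 12.9, adjusted p = 8.6e-09). Immediate early genes were higher in 13 of 22 cases and lower in 1 (camera adjusted p = 0.0015; adjusted p = 0.056 with an estimated correlation). Transcription factor genes were higher in 15 of 26, with 1 lower (camera adjusted p = 0.0011; adjusted p = 0.056 with an estimated correlation). The mast cell protease gene Cma1 measured 473 ± 577 and was listed at 0 after PBS, and the muscle actin gene Acta1 measured 2.74 ± 6.13 against 2320 ± 782. Of all genes 3091 passed, 2195 higher and 896 lower. TMM scaling moved the median of all genes from 0.231 to -0.013 and gave 1350 higher and 1507 lower. The count was 1762 and 1825 without PBS libraries 1 and 2.

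Between the injection days among poly I:C newborns (E12.5, n = 5, against E14.5, n = 2), immediate early genes were higher after E12.5. Fosb measured 1600 ± 300 and 214 ± 33.3 (log2 change 2.89, SE 0.17, limma adjusted p = 1.7e-10), and 16 of 22 list members were higher and 1 lower (camera adjusted p = 6.3e-10, and 0.009 with an estimated correlation). B2m measured 35900 ± 3130 and 10200 ± 2020 (1.83, adjusted p = 4.9e-11). The cytokine gene Il1b measured 205 ± 114 and 5.2 ± 7.3, and the granulocyte gene S100a9 372 ± 415 and 2.1 ± 2.9 (adjusted p = 1.2e-05 and 2.2e-06). Of 9 monocyte and granulocyte genes 7 were higher (camera adjusted p = 2.5e-05; adjusted p = 0.37 with an estimated correlation). Altogether 1662 genes passed, 1104 higher and 558 lower after E12.5, against 784 and 798 under TMM scaling, which moved the median of all genes from 0.112 to -0.016. Without E14.5 libraries 1 and 2 the counts were 821 and 763. Both comparisons with the E12.5 newborns run across library sets: Gapdh, Ppia and Gpx4 summed to at most 38 in those libraries and to at least 3079 in the E14.5-injected newborns.

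**Figure D2:**
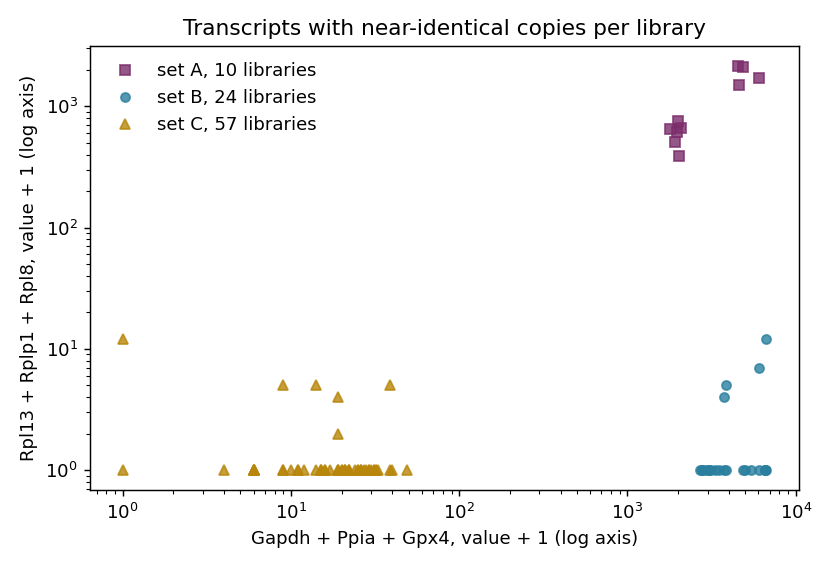
Sum of Gapdh, Ppia and Gpx4 against the sum of Rpl13, Rplp1 and Rpl8 (tags per 10000000) in each of the 91 libraries. The libraries fall into 3 sets: 10 with ribosomal sums of 391 to 2145, 24 with ribosomal sums of at most 11 and the other sum at 2685 or more, and 57 with both sums low (at most 11 and 48).

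At 4 weeks after injection at E14.5 (n = 12 against 2), 5 genes were higher in the poly I:C group and 0 lower of 9038. Myc, a growth regulator, measured 385 ± 87.2 against 115 ± 81.7 (log2 change 1.90, limma adjusted p = 0.0077), Trib1 939 ± 153 against 367 ± 228 (1.49, adjusted p = 0.0077) and Plekhg2 117 ± 31.1 against 22 ± 11 (2.39, adjusted p = 0.015). Dusp8 measured 47.5 ± 23.8 against 2.47 ± 3.49 (adjusted p = 0.024) and the ubiquitin-conjugating enzyme gene Ube2e1 579 ± 76.4 against 280 ± 71.8 (1.06, adjusted p = 0.033). Monocyte and granulocyte genes rose in 0 of 16 cases over all genes and in 14 adjusted over the list alone (median log2 change 1.8, camera adjusted p = 1.2e-14; adjusted p = 0.32 with an estimated correlation). Tmem119 and Cx3cr1 did not pass (adjusted p = 0.82 and 0.56). The 12 libraries carry the tags m1 or m2 (6 each), whose meaning the labels do not state, so whether they are independent is not known. With reads summed per tag 0 genes passed, and Myc, Trib1, Plekhg2 and Ube2e1 changed by 1.92, 1.52, 2.43 and 1.05 without passing. At an unadjusted p under 0.05 there were 751 genes by limma, and edgeR called 0 genes, with 738 at that level. PBS library 1 decided these calls: without it the changes of Myc, Trib1, Plekhg2, Dusp8 and Ube2e1 were 1.12, 0.81, 1.90, 2.91 and 0.79 and none of the 5 passed, while 14 genes passed in all. Dusp8 also failed without poly I:C library 4 (4.18), and Ube2e1 without poly I:C library 3 (1.06), 4 (1.05), 9 (1.05) or 12 (1.06). The count was 49 without PBS library 2, and 20, 3, 8 and 10 without poly I:C libraries 1, 4, 6 and 10.

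The effect of E14.5 poly I:C differed between newborns and 4 weeks for 244 of 9469 genes, by the test of the interaction. Ccr5 was at 3060 ± 385 and 2930 ± 84.7 in the poly I:C and PBS groups at 4 weeks, so that its effect was lower by 3.55 than in newborns (log2 difference of effects -3.55, SE 0.26, limma adjusted p = 8.3e-09). Nfe2l2 (-3.09, adjusted p = 9.1e-07), P2ry13 (-2.09, adjusted p = 4.3e-06) and Cx3cr1 (-1.27, adjusted p = 0.00058) went the same way. Ngp went the other way, at 9770 ± 5650 and 2630 ± 1590 at 4 weeks and 5.54 and 569 in newborns (adjusted p = 4.4e-05). In all, 7 of 16 monocyte and granulocyte genes had a more positive effect at 4 weeks (camera adjusted p = 3.4e-14; adjusted p = 0.078 with an estimated correlation). Effects were more positive at 4 weeks for 68 genes and more negative for 176. Newborn and 4-week libraries belong to different library sets, and the count was 150 and 122 without PBS newborn libraries 1 and 2, 115 and 109 without poly I:C newborn libraries 1 and 2, and 108 without PBS 4-week library 1.

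The germ-free groups address the role of the microbiota. Newborns from germ-free housing (n = 3 against 3) had higher transcription factor genes in 9 of 27 cases and lower in 0 (12 and 1 adjusted over the list alone, camera adjusted p = 6.8e-05; adjusted p = 0.073 with an estimated correlation). Klf4 measured 2600 ± 320 against 308 ± 85.9 (log2 change 3.10, SE 0.29, limma adjusted p = 1.6e-07) and Klf2 2060 ± 68.2 against 340 ± 5.89 (2.59, adjusted p = 1.6e-07). The phosphatase gene Dusp1 measured 5350 ± 236 against 1310 ± 563 (2.11, adjusted p = 6.4e-06) and Ddit4 1460 ± 254 against 92.6 ± 20.4 (3.97, adjusted p = 0.00061). Lower were the lectin gene Cd72 (184 ± 38.7 against 954 ± 185, adjusted p = 0.0071), the tetraspanin gene Cd9 (3670 ± 177 against 6310 ± 147, adjusted p = 0.00032) and the MHC class I gene H2-D1 (4630 ± 445 against 7980 ± 441, log2 change -0.79, adjusted p = 7.2e-05). Immediate early genes rose in 10 of 24 cases and fell in 0 (13 and 1 adjusted over the list alone; median log2 change 0.88, camera adjusted p = 2.3e-12; adjusted p = 0.07 with an estimated correlation). Damage-associated genes fell in 4 of 24 cases and rose in 0 (10 adjusted over the list alone; median -0.40, camera adjusted p = 2.7e-08, and 0.002 with an estimated correlation). Of 26 homeostatic genes 8 rose, Tmem119 among them (11100 ± 852 against 6590 ± 739, adjusted p = 0.0016), and 0 fell (camera adjusted p = 6.8e-05; adjusted p = 0.073 with an estimated correlation). Of 9433 genes 569 passed, 458 higher and 111 lower, and edgeR called 438 (411 shared). Without germ-free library 2 the count was 374.

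At 4, 6 and 8 weeks, interferon-response and MHC class I genes were lower in germ-free animals. H2-D1 was lower at all 3 ages: 4640 ± 192 against 10000 ± 552 at 4 weeks (n = 2 and 2; log2 change -1.11, limma adjusted p = 0.00011), 3710 ± 331 against 7550 ± 515 at 6 weeks (n = 5 and 4; -1.03, adjusted p = 2.2e-07) and 4770 ± 15.8 against 9120 ± 747 at 8 weeks (n = 2 and 2; -0.93, adjusted p = 0.0013). At 4 weeks the interferon-induced Ifit2 measured 11.4 ± 10 against 195 ± 53.3 (-4.26, adjusted p = 0.013; -3.29 and no longer passing without germ-free library 2, -3.98 and no longer passing without control library 1). The receptor tyrosine kinase gene Axl measured 30.7 ± 2.9 against 328 ± 124 (-3.33, adjusted p = 0.0013; -2.93 and no longer passing without control library 1). At 6 weeks Rsad2 measured 4.82 ± 3.15 against 93.5 ± 45 (-4.04, adjusted p = 0.0036), Axl 94.6 ± 39.9 against 379 ± 242 (adjusted p = 0.0068) and Gpr84 534 ± 102 against 1380 ± 184 (-1.38, adjusted p = 4.5e-05). Klf2 was higher (769 ± 198 against 353 ± 56.4, adjusted p = 0.0068). At 8 weeks Cd52, a surface glycoprotein gene, measured 454 ± 172 against 1760 ± 113 (-2.01, adjusted p = 0.0013).

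The interferon-response list was lower at each of these ages with both correlations. At 4 weeks 4 of 30 members fell and 0 rose (13 adjusted over the list alone; median log2 change -0.99, camera adjusted p = 4.9e-13, and 0.0016 with an estimated correlation). At 6 weeks 9 fell (21 adjusted over the list alone; median -1.48, camera adjusted p = 1.1e-33, and 2.4e-05), and at 8 weeks 2 fell (6 adjusted over the list alone; median -0.77, camera adjusted p = 5.6e-11, and 0.0052). MHC class I genes fell in 2 of 13 cases at each age (6, 6 and 4 adjusted over the list alone; camera adjusted p = 5e-12, 4.4e-12 and 2.7e-06, and 0.0012, 0.0012 and 0.016 with an estimated correlation). Inflammatory genes fell in 3 of 26 cases at 4 weeks and 2 of 26 at 6 weeks (camera adjusted p = 5.7e-06 and 3.6e-06, and 0.012 and 0.0082 with an estimated correlation). At 6 weeks 1 of 8 MHC class II genes fell (5 adjusted over the list alone, camera adjusted p = 2.5e-07, and 0.0013). The counts of genes were 40 at 4 weeks (10 higher, 30 lower), 38 at 6 weeks (6 higher, 32 lower) and 24 at 8 weeks (12 higher, 12 lower; 9 and 19 under TMM scaling, which moved the median of all genes from 0.147 to -0.002). At 4 weeks 11 genes passed without control library 1, and at 6 weeks 20 without control library 2. At 8 weeks 15 passed without germ-free library 1, 132 without germ-free library 2 and 15 without control library 2. With only both 8-week groups in the fit 1 gene passed, Cd52, and H2-D1 (-0.93) did not.

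**Figure D3:**
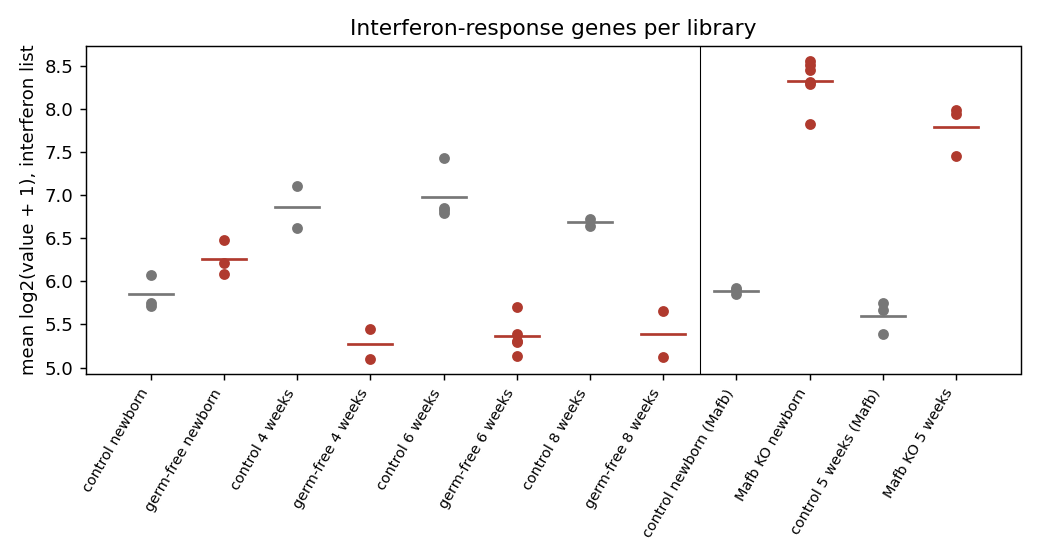
Mean log2(value + 1) of the interferon-response list in each library of the germ-free and Mafb tables, by group on the horizontal axis, with a bar at the group mean. Control library 3 at 6 weeks lies at 7.43 against 6.80 to 6.85 in its group, and newborn Mafb knockout library 4 at 7.83 against 8.29 to 8.56.

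The mean germ-free effect at the 3 later ages differed from that in newborns for 250 genes, 56 more positive and 194 more negative later. Interferon-response genes had the more negative effect later in 7 of 30 cases (17 adjusted over the list alone; median difference -1.61, camera adjusted p = 1.1e-14, and 0.0026 with an estimated correlation), among them Irf9 (-1.70, limma adjusted p = 0.00012) and Rtp4 (-2.39, adjusted p = 0.001). Klf4 (-2.9, adjusted p = 3.4e-05), Klf2 (-2.14, adjusted p = 0.00012) and Dusp1 (-1.86, adjusted p = 0.001) likewise had the more negative effect later. Immediate early genes had the more negative effect in 8 of 24 cases (camera adjusted p = 3.5e-09; adjusted p = 0.13 with an estimated correlation). The count was 152 and 139 without germ-free newborn libraries 1 and 2. The Y-linked gene Ddx3y was listed at 0 in all groups of 4 and 8 weeks and at most 9.36 at 6 weeks, against 213 to 234 in newborn controls and 24, 308 and 320 in germ-free newborns. Sex of the animals therefore appears to differ between ages and, by 1 library, between the newborn groups.

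Mafb itself was low in every library labelled as knockout. In newborns it measured 20.8 to 80.1 (8 to 27 reads) in 6 knockouts and 1990 to 2410 in 3 controls, and at 5 weeks 108 to 144 in 3 knockouts and 8090 to 8940 in 3 controls. The log2 change was -6.01 (SE 0.29, limma adjusted p = 1.8e-11) in newborns and -6.13 (SE 0.34, adjusted p = 9.9e-11) at 5 weeks. Newborn knockouts expressed interferon-response genes at higher levels. Oas2, an antiviral enzyme gene, measured 2250 ± 572 against 118 ± 21.9 (4.21, adjusted p = 1.5e-09), Ifit1 209 ± 56.3 against 17.8 ± 9.62 (3.6, adjusted p = 1.8e-07) and Isg15 186 ± 50.5 against 20.3 ± 12.0 (3.21, adjusted p = 9.3e-06). Of 32 list members 30 rose and 0 fell (32 adjusted over the list alone; median log2 change 2.32, camera adjusted p = 6.3e-73, and 0.00068 with an estimated correlation). MHC class I genes rose in 10 of 13 cases (12 adjusted over the list alone; median 1.49, camera adjusted p = 7.6e-28, and 0.0043), with H2-D1 at 19800 ± 2680 against 4500 ± 667. Axl rose by 1.94 (4720 ± 487 against 1220 ± 60, adjusted p = 4.6e-09). Homeostatic genes fell in 8 of 26 cases and rose in 0 (median -0.20, camera adjusted p = 2.5e-10, and 0.012), including P2ry12 (8360 ± 1060 against 16800 ± 815, adjusted p = 6.9e-07) and Fcrls (12400 ± 1240 against 22900 ± 2330, adjusted p = 7.4e-06). Tmem119 and Sall1 did not pass (adjusted p = 0.95 and 0.37). The protease gene Bmp1 fell to 45.4 ± 10 from 294 ± 25.1 (-2.70, adjusted p = 1.2e-07). In newborns 406 of 8768 genes passed, 265 higher and 141 lower, and edgeR called 493 (391 shared). Without control library 1 the count was 261.

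At 5 weeks the knockouts (n = 3 against 3) again had higher interferon-response genes, with 29 of 32 raised and 0 lowered (30 adjusted over the list alone; median log2 change 2.19, camera adjusted p = 1.5e-27, and 0.037 with an estimated correlation). Oas2 measured 1550 ± 672 against 46.4 ± 16.2 (5.0, limma adjusted p = 1.1e-09), Axl 3580 ± 928 against 209 ± 29.6 (4.1, adjusted p = 2e-13) and the complement gene C2 369 ± 100 against 4.75 ± 0.702 (5.98, adjusted p = 7.2e-14). Damage-associated genes rose in 9 of 24 cases and fell in 1 (13 and 1 adjusted over the list alone, camera adjusted p = 5.1e-05; adjusted p = 0.12 with an estimated correlation), with Cst7 at 763 ± 225 against 101 ± 35.9 and Apoe at 5350 ± 1130 against 2170 ± 47. Cell cycle genes rose in 16 of 32 cases and fell in 0 (camera adjusted p = 9.8e-06; adjusted p = 0.11 with an estimated correlation), from low levels: Aurkb measured 31.4 ± 8.71 against 7.19 ± 2.6. Homeostatic genes fell in 9 of 26 cases and rose in 1 (camera adjusted p = 0.00011; adjusted p = 0.11 with an estimated correlation), with Fcrls at 6360 ± 286 against 23200 ± 2210 (-1.86, adjusted p = 1.4e-09) and Cx3cr1 at 22400 ± 10900 against 47100 ± 312. Gpr34 measured 314, 629 and 3740 in knockout libraries 1, 2 and 3 and 6550 ± 788 in controls (adjusted p = 0.00097). Of all genes 1312 passed, 739 higher and 573 lower, or 666 and 700 under TMM scaling, which moved the median of all genes from 0.119 to 0.031. With only both 5-week groups in the fit 319 passed, and without knockout libraries 1 and 2 together 318. Knockout library 3 differed from the other knockouts: the count was 2944 without it, 658 and 582 without knockout libraries 1 and 2, and 779, 784 and 783 without controls 1, 2 and 3.

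The knockout effect differed between the ages for 63 genes, 34 more positive and 29 more negative at 5 weeks. C2 (log2 difference of effects 2.88, SE 0.28, limma adjusted p = 7.9e-06), Axl (2.1, adjusted p = 7.9e-06) and Spp1 (3.71, adjusted p = 0.012) had the more positive effect at 5 weeks, and Fcrls the more negative (-0.97, adjusted p = 0.0081). Damage-associated genes were more positive at 5 weeks in 4 of 24 cases (11 adjusted over the list alone; median 0.64, camera adjusted p = 3.2e-10; adjusted p = 0.077 with an estimated correlation). None of the 32 interferon-response genes differed between the ages over all genes or adjusted over the list alone, 0 and 0 (limma; camera adjusted p = 0.025; adjusted p = 0.75 with an estimated correlation). The count ranged from 21 to 41 without any 1 of knockout 5-week libraries 1 and 2, control 5-week libraries 1, 2 and 3, newborn knockout libraries 1, 2, 3 and 4, or newborn control libraries 1, 2 and 3, and was 1322 without knockout 5-week library 3.

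Lists of up to 100 genes that separate the developmental classes, taken from the Timeline comparisons, were then tested in the perturbations. Genes higher in yolk sac than in early brain were raised in newborn Mafb knockouts, with 35 of 79 higher and 2 lower (median log2 change 0.63, camera adjusted p = 8.4e-29, and 0.0092 with an estimated correlation). They were lowered in germ-free animals at 4, 6 and 8 weeks (6, 5 and 2 of 81 lower; median -0.37, -0.28 and -0.20; camera adjusted p = 1.3e-06, 9e-08 and 5.1e-06, and 0.0027, 0.0012 and 0.0042). That list shares 11 genes with the interferon-response list and 6 with MHC class I. Only members of these fixed lists were counted, so further interferon-induced genes in the yolk sac list would be missed. Its shifts are therefore not shown to be separate from those of the interferon-response genes. In knockouts at 5 weeks the yolk sac list was higher too (42 of 79, 1 lower, camera adjusted p = 4.7e-12, and 0.14 with an estimated correlation). So were genes higher in later brain than in adults (32 of 96, 2 lower, camera adjusted p = 7.6e-07, and 0.14). The list of genes higher in later brain than in adults shares 19 genes with the cell cycle list. After poly I:C at E14.5, genes higher in early brain than in yolk sac were raised in newborns in 23 of 95 cases and lowered in 3 (camera adjusted p = 0.00034, and 0.1 with an estimated correlation). Of these listed genes 12 are also in the homeostatic list. In germ-free newborns, genes higher in later than in early brain were raised in 25 of 99 cases and lowered in 3 (camera adjusted p = 0.00011, and 0.4 with an estimated correlation). That list shares 10 genes with the homeostatic list and 5 with the immediate early list. Of 78 such tests 27 passed, 5 of them with an estimated correlation.

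**Figure D4:**
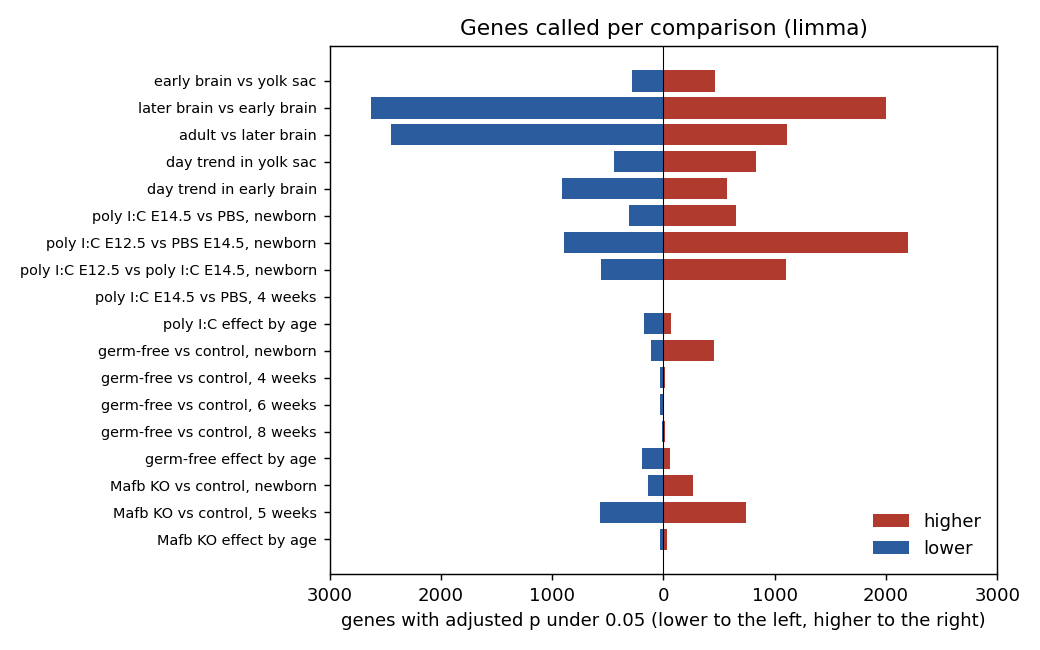
Number of genes called higher and lower in each of the 18 comparisons that have a direction (limma, adjusted p under 0.05), with higher to 1 side of 0 and lower to the other. Later against early brain gave the most, 2003 higher and 2631 lower, and poly I:C at 4 weeks the fewest, 5 higher.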

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

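The tests of copies, poly I:C, depth, PBS libraries, microglia share, GC content, TMM scaling and the Mafb knockout libraries (including the reading of their counts) were chosen after the result was seen. Chance places about 1 in 20 groups beyond the limit used here for a library far from its group, and 6 of 80 sets of values were found beyond it.

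Gapdh, Ppia and Gpx4 were near 0 in 57 libraries (all of the germ-free and Mafb tables, and in the poly I:C table the E12.5 newborns and the 4-week animals) and abundant in 34. Poly I:C at E12.5 cannot be the cause, since the sum of the 3 genes was at most 30.4 in 6 untreated newborn controls against at least 3722 in PBS newborns, and depth cannot either, since at least 281 reads were expected and at most 24 were seen. Reads shared with near-identical copies remain a candidate explanation: 69.2% of 13 genes present in the E14.5-injected newborns and near 0 in the other 20 newborn libraries had a copy, against 6.98% of all genes searched. A change in how reads with several matches were kept between sets of libraries could give this split, and no label records it.

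The E14.5-injected newborn libraries stood apart from other newborns. Genes that differed at 2-fold between the E12.5 newborns and 1 PBS library moved the same way in at least 85.1% of cases between untreated newborns of other tables and the other PBS library, where 66.2% to 66.6% of all genes were higher in the untreated newborns. Part of the difference between E12.5 and PBS newborns may belong to these libraries whatever the treatment. Skeletal muscle RNA may be part of it, although the CD45int CD11Bint gate would remove muscle cells: 94.7% of the 19 further muscle genes detected were higher after PBS than after poly I:C at E12.5 (sums of 892 to 1160 against 233 to 389; 321 to 898 after poly I:C at E14.5). A lower share of microglia made up by more of all other cells alike in the PBS libraries is argued against, since their markers moved apart. After E12.5, 4 of 7 neuron markers were higher and 0 lower (median log2 change 1.47). Endothelial and astrocyte medians were 0.16 and 0.17. The 20 muscle genes summed to 59 to 148 after E12.5 against 8693 and 12887 after PBS. A lower share made up by muscle alone therefore stays open, and the comparison runs across library sets. An effect of injection day stays open, as the E12.5 group has no PBS control.

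In Mafb knockouts at 5 weeks 573 genes were lower, and knockout library 3 differed from libraries 1 and 2 in them (median log2 change from controls -0.45 against -1.49 and -1.39). The lower genes had a median GC content of 36% at their transcript ends, against 47.2% for the higher genes and 43.5% for all genes tested. GC content as the whole cause is argued against, since 401 of the lower genes still passed after each library's GC trend was removed (median -1.18 before and -1.03 after). A part played by GC content is not excluded. Scaling is argued against too, since 700 genes were lower under TMM. A difference between knockout libraries other than Mafb is a candidate explanation: the count was 2944 without library 3 against 658 and 582 without libraries 1 and 2, which hold 59.6% and 59.3% of the scaled tags in genes against 48% to 52.7% in the other 13 libraries. Loss of Mafb cannot be told apart from it, with 52.3% of 969 genes lower in libraries 1 and 2 also lower in library 3 than in all 3 controls. The share without any effect is not known here, since these genes were chosen against the same controls. Interferon-response genes showed the split too (median log2 change 2.35 and 2.3 in libraries 1 and 2 and 1.72 in library 3), and 32 of 32 were higher in library 3 than in all 3 controls.

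The effect of treatment differed between ages by the test of the interaction for 244 genes (poly I:C), 250 genes (germ-free) and 63 genes (Mafb).

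Single libraries lay far from their groups as follows. In the germ-free controls at 6 weeks, library 3 had Sall1 at 3520 against 1980 to 2180 and an interferon-response mean of 7.43 against 6.80 to 6.85, and library 1 had Mki67 at 6.69 against 0 in the others. In newborn Mafb knockouts, library 6 had Tmem119 at 8890 against 7250 to 7840, library 4 had an interferon-response mean of 7.83 against 8.29 to 8.56, and library 3 had 4446774 reads in genes against 1670000 to 2190000.

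Other splits of the same libraries were used to ask whether a random grouping would call as many genes, counting such splits with the real one included. Libraries were moved singly, as if independent, which the labels do not state. If they are, random grouping is argued against for germ-free at 6 weeks (1 of 100 splits, 38 genes, highest other 11). The same holds for newborn Mafb knockouts (1 of 84, 406 genes, highest other 28). For the Timeline classes the splits cannot decide, since libraries of the same stage were moved apart. The real count was reached in 1 of 100 splits for later against early brain (4634 genes, highest other 3020). It was likewise 1 of 100 for adult against later brain (3553, highest other 1960). For early brain against yolk sac it was 2 of 100 (747). The highest other split there, with 792 genes, kept 5 of 7 brain and 6 of 8 yolk sac libraries in place. That split put both brain libraries of E10.5 with the yolk sac of E10.5 and E11.5. With embryonic day as a factor the count was 1222. Splits are too few in germ-free newborns (1 of 10; 569, highest other 4) and Mafb knockouts at 5 weeks (1 of 10; 1312, highest other 192). For the Mafb interaction (5 of 100; 63) the splits cannot decide: the highest other, 357, kept all 5-week libraries in place and exchanged newborns, so that the knockout effect of 1 age remained in it.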

How the results depend on the processing

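The alternatives named in the methods as chosen after seeing the data are edgeR, TMM, library sets, copies, GC, the omission of Mafb knockout 5-week libraries 1 and 2 and the omission of the 20 muscle genes. Over all alternatives 305 of 394 counts stayed within 1.5 times of the reported one and 89 did not, and 18271 of 19902 values of 956 named gene results kept direction and side of the threshold, 1625 lost the call and 6 reversed. Except where a construction is named, the cause was not tested.

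Early brain against yolk sac (747) gave 1248 with no filter, 1262 by DESeq2, 1144 by edgeR, 1187 without libraries under the depth threshold, 226 with only both classes fitted (fewer samples), 2343 with a mean for each stage and 1222 with embryonic day as a factor. Rpl13 was 0.00 with the library set as a block and 0.00 without brain E11.5 and E12.5. The early brain trend (1484) gave 0 by limma without both E10.5 libraries (fewer samples; 2058 at an unadjusted p under 0.05), with Rps5 at -0.03. Adult regions (114) gave 3 with no filter. Poly I:C at 4 weeks (5) gave 12 with a pseudocount of 0.1, 16 by DESeq2, 0 by edgeR (738 at an unadjusted p under 0.05), 10 with m1 and m2 (tags of unstated meaning on the 12 libraries) as groups and 0 by limma with reads summed per m tag (799 at an unadjusted p under 0.05). Germ-free at 4 weeks (40) gave 61 by DESeq2 and 152 with only both groups; at 6 weeks (38) 106 by DESeq2 and 69 by edgeR; at 8 weeks (24) 11 with no filter, 11 by edgeR and 1 with only both groups. Mafb at 5 weeks (1312) gave 319 with only both groups and 318 without knockouts 1 and 2, where Dbi was 0.00, Abca1 0.06 and Hsp90aa1 0.18; by age (63) it gave 38 with no filter, 152 by DESeq2 and 38 without knockouts 1 and 2. With an estimated correlation 28 gene lists of 129 and 5 developmental lists of 27 passed.

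Leaving out 1 library gave 475 to 873 for early brain against yolk sac, 558 to 1364 for the yolk sac trend, 828 to 1347 for the early brain trend, 54 to 96 for adult regions, 331 to 447 for poly I:C at E14.5 in newborns, 1762 to 3065 at E12.5 against PBS, 763 to 1650 between injection days, 3 to 49 at 4 weeks and 108 to 304 by age, 374 to 487 for germ-free newborns, 11 to 40 at 4 weeks, 20 to 34 at 6 weeks, 15 to 132 at 8 weeks and 139 to 269 by age, and 261 to 379 for Mafb newborns, 582 to 2944 at 5 weeks and 21 to 1322 by age. For later against early brain (4208 to 4988) and adults (3283 to 3484) no library moved the count by over 1.5 times.

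Label numbers were not taken to pair the samples: same-numbered samples correlated at -0.09 to 0.1, with 0 pairs over 0.1. Such weak correlations do not exclude pairing. With the replicate block the counts were 172 for adult regions (6 of 6 pairs correlated best with their own letter) and 212 for Mafb newborns. For poly I:C at E14.5 in newborns the count was 1694 (2 of 2 pairs best with their own number). In groups of 2 libraries the deviations from the group mean mirror each other, so both labels give the same correlation by construction. These shares therefore repeat the same values (0.02 to 0.04 for adult regions, 0.05 for poly I:C) and cannot decide on pairing. In the poly I:C fit with the block the E12.5 newborns no longer added to the spread. Within 1.5 times of the reported counts were 1089 for early brain against yolk sac, 2714 for poly I:C at E12.5 and 1616 for Mafb at 5 weeks. Also within it were 628, 35, 27 and 31 for germ-free newborns and at 4, 6 and 8 weeks. Depth limits brain E10.5 most, where 1 read is worth about 21 units.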

Other observations

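Haemoglobin transcripts were not confined to yolk sac: Hbb-bs reached 6140 to 11600 in brain at E13.5, E14.5 and E16.5 and 10500 and 14100 in yolk sac at E13.5. The single brain library of E13.5 held Mrc1 at 376, against a mean of 4540 ± 959 in brain at E10.5 (n = 2). In 4-week animals of the poly I:C table the neutrophil gene Ngp ranged from 1500 to 3750 after PBS (n = 2). After poly I:C it ranged from 3320 to 18300 (n = 12).

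The Y-linked gene Ddx3y varied within some groups, so that libraries of both sexes of animals appear to share these: it measured 18.8 and 720 in PBS newborns, 10.4 and 212 in newborns after poly I:C at E14.5, 24, 308 and 320 in germ-free newborns, 5.41, 8.59 and 618 in Mafb knockouts at 5 weeks and 9.73, 0 and 706 in their controls. In the germ-free table it was 0 in all 4 groups at 4 and 8 weeks, at most 9.36 at 6 weeks, where columns are labelled female, and 213 to 234 in newborn controls. Sex was not part of any comparison.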
